A study of Mus musculus with 34 samples.

How the data were processed

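Stranded total RNA from mixed, powdered quadriceps and gastrocnemius muscle of male mice was sequenced in 34 libraries, 1 per mouse, which fall into 4 groups lacking genes in skeletal muscle and 4 groups of floxed controls. The groups were taken from the labels alone. Replicate numbers count the libraries within each group and do not pair knockout with control mice. The deposited file gives raw counts per Ensembl gene, for 46071 genes and 1 column per library, and all of its columns were used. According to the processing notes, the authors aligned reads to GRCm38 with STAR and counted them with featureCounts. The notes give no tool versions, annotation release or strand setting. The values are whole numbers, and the deposited counts carry no normalization. Total counts ran from 1499025 to 7581198 per library, and this depth sets the counting precision of weakly expressed genes. Of the gene IDs, 45143 matched a symbol in the GENCODE M21 annotation of GRCm38.

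Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and data.table (1.17.8), and figures were drawn in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Genes were kept by edgeR's filterByExpr with the 8 groups, which left 13646. Library totals were scaled by trimmed mean of M values (TMM) factors, and CPM values use the scaled totals. A model with 1 mean per group was fitted to all 34 libraries by edgeR's quasi-likelihood method with robust shrinkage. Each knockout group was compared with the floxed controls of its own colony. Further tests took the difference between the QKO and MIGIRKO changes, the difference between the MIGIRKO and MIRKO changes, QKO against MIGIRKO directly, and the 4 floxed groups against each other. Adjusted p-values are Benjamini-Hochberg values over the tested genes, and a gene is called at an adjusted p under 0.05. Errors of log2 changes are standard errors (SE), worked back from each test as the size of the change over the square root of its F statistic. Errors of CPM are standard deviations (SD) between the libraries of a group. For genes with few counts in a group, CPM carries counting error as well, and the fitted change depends on the prior count.

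Altogether 35 gene lists with 804 entries, for the respiratory chain, energy metabolism, muscle fibers, signalling, protein turnover and the other cell types of muscle, were written before the data were examined. Each list with at least 5 tested members was tested with limma's camera on voom values, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. With the estimated correlation none of the lists was called in any of the 7 comparisons. Its adjusted p stands beside each list given as called at the preset correlation. Members were also counted with p-values adjusted over the list alone. Named genes followed a rule fixed before the data were examined. It took the targeted genes, up to 8 called genes in each direction with the largest change and an average log2 CPM of at least 1, and up to 4 called members of each list with the smallest adjusted p, or the 1 with the smallest if none was called. It also took Nnt and genes of the sex chromosomes.

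The alternatives fixed beforehand were the DESeq2 test, DESeq2 size factors, the limma-voom test, no filter, a filter of CPM above 1 in at least 3 samples, the 6 runs of consecutive library numbers as a block, all 12 floxed libraries as control, fits to the compared groups only, and leaving out each library in turn. Those added after the data were seen were library totals with no scaling factor, leaving out the libraries labelled MIRKO 4 and MIGIRKO 6, and leaving out QKO 5 and QKO 6. Groups were also compared over other splits of their libraries, at most 100 per comparison. The procedure was tested on simulated data in which 200 genes were changed, divided over 3 sizes of change. Of the 67 genes changed 2-fold, it recovered 55.2% for MIRKO, 47.8% for MIGF1RKO, 52.2% for MIGIRKO, 38.8% for QKO and 22.4% for the difference between the QKO and MIGIRKO changes. No paired analysis was possible because the labels give no pairs of littermates.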

Results

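Skeletal muscle RNA was measured in 4 genotypes of knockout mice and in the floxed controls of each. By their labels, MIRKO mice (n = 4) lacked the insulin receptor in muscle, MIGF1RKO mice (n = 5) the IGF-1 receptor, MIGIRKO mice (n = 6) both receptors, and QKO mice (n = 7) both receptors together with the transcription factors FoxO1, FoxO3 and FoxO4, which insulin signalling holds out of the nucleus. Their controls carried the floxed alleles only and are called IRlox (n = 3), IGFRlox (n = 4), IRIGFRlox (n = 3) and Qlox (n = 2). Total counts were 3880455 to 6117074 in IRlox, 4092536 to 5349779 in MIRKO, 3727904 to 6050260 in IGFRlox and 3295702 to 5084892 in MIGF1RKO. They were 5279473 to 7581198 in IRIGFRlox, 4652877 to 5969877 in MIGIRKO, 3439749 to 4764528 in Qlox and 1499025 to 6605874 in QKO. The scaling factor was 1.23 ± 0.05 (SD) in MIGIRKO and 1.14 ± 0.11 in MIRKO, and its mean lay between 0.876 and 0.965 in the other groups. Myh4, the fast myosin of type 2B fibers, took 3.41% ± 0.74 of counts in MIGIRKO and 6.75% ± 0.22 in IRIGFRlox.

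The targeted genes showed whether each deletion is visible in whole-gene counts. Insr, the insulin receptor (ENSMUSG00000005534, chromosome 8, 3122061 to 3279617, GRCm38), fell in every genotype in which it was targeted. Its log2 change was -1.83 ± 0.17 (SE) in MIRKO (adjusted p = 1.9e-08), -1.68 ± 0.15 in MIGIRKO (adjusted p = 2.0e-09) and -1.99 ± 0.16 in QKO (adjusted p = 2.7e-10). In CPM, Insr was 42.5 to 50.7 in MIRKO and 146 to 172 in IRlox, 40.7 to 69.8 in MIGIRKO and 159 to 191 in IRIGFRlox, and 27.8 to 46.1 in QKO and 141 to 163 in Qlox. In MIGF1RKO, where Insr was not targeted, its change was -0.17 (adjusted p = 0.78).

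Igf1r, the IGF-1 receptor (ENSMUSG00000005533, chromosome 7, 67952827 to 68233668), was called lower in QKO, with a log2 change of -1.09 ± 0.25 (adjusted p = 0.027). That call was lost with library runs as a block (adjusted p = 0.087), with library totals only (0.12), with the compared groups only (0.25), and without QKO 1, Qlox 1 or Qlox 2. In MIGF1RKO, Igf1r was 9.83 ± 1.41 CPM against 16.5 ± 2.91 in IGFRlox, a log2 change of -0.75 ± 0.21 that missed the threshold (adjusted p = 0.10). It was called with all 12 floxed libraries as control (-0.79, adjusted p = 0.0086) and with the compared groups only (-0.74, adjusted p = 0.049). In MIGIRKO, Igf1r was 18.6 ± 3.97 CPM against 18.6 ± 1.94 in IRIGFRlox (log2 change 0.00 ± 0.21, adjusted p = 0.99), so a loss of its transcript was not detectable at whole-gene level. The deleted exons are not given, and cells other than muscle fibers keep the gene. Both hold for QKO and MIGF1RKO as well, where Igf1r counts were lower (short of the threshold in MIGF1RKO). Markers of fat, nerve and immune cells were higher in MIGIRKO, however, so such cells may have given more of its Igf1r counts, which was not tested. These counts do not show the Igf1r deletion in MIGIRKO.

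Among the FoxO genes, Foxo4 (ENSMUSG00000042903, chromosome X, 101254528 to 101260873) was 6.56 ± 1.97 CPM in QKO and 152 ± 11.5 in Qlox, 23.8-fold lower (adjusted p = 2.8e-18). Foxo1 (ENSMUSG00000044167, chromosome 3, 52268336 to 52353221) was 18.2 ± 5.01 CPM and 140 ± 11.8 CPM in these groups, 7.87-fold lower (adjusted p = 4.9e-06). Foxo3 (ENSMUSG00000048756, chromosome 10, 42181841 to 42276755) was 113 ± 15.0 CPM in QKO and 91.6 ± 16.7 in Qlox (adjusted p = 0.71), so these counts do not show the Foxo3 deletion in QKO. Foxo4 also fell in MIGIRKO, with a log2 change of -0.73 ± 0.17 (adjusted p = 0.0010), but not with library totals only (-0.25, adjusted p = 0.19). Xist, the RNA that silences an X chromosome in females, had at most 3 counts in any library. Nnt, a mitochondrial enzyme whose genotype varied among these mice, ran from 23.6 to 176 CPM over the libraries and was called in none of the comparisons (largest difference in MIRKO, -1.28 ± 0.50, adjusted p = 0.19).

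**Figure D1:**
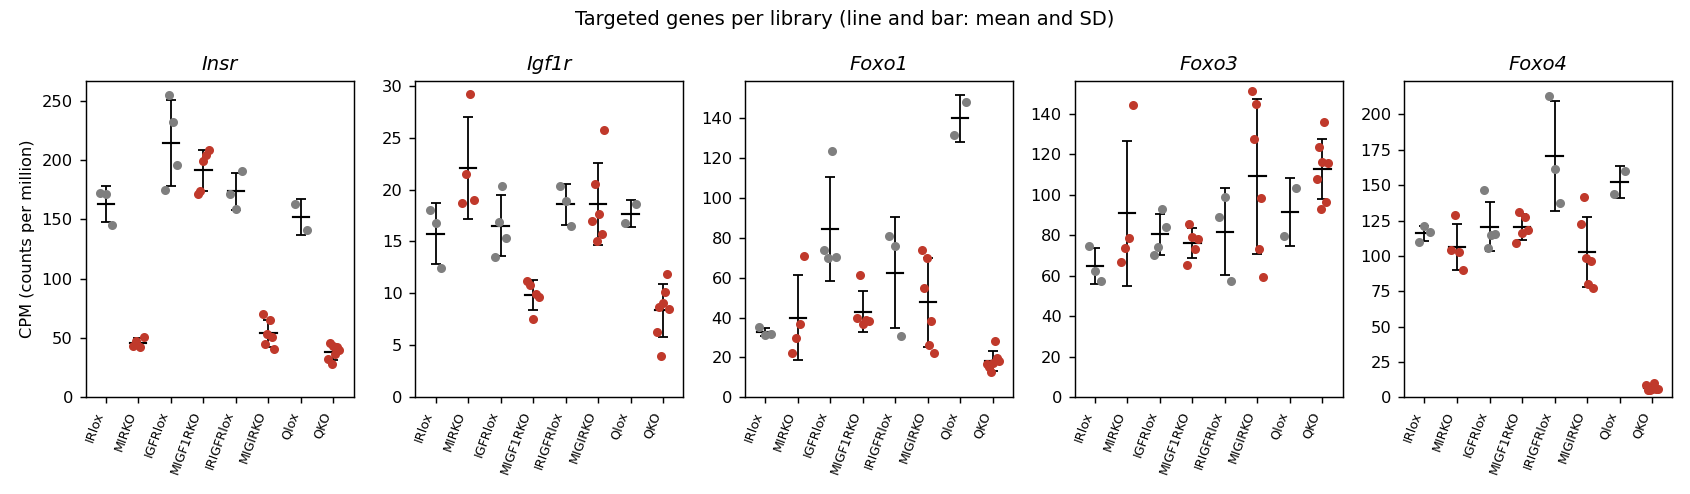
CPM of Insr, Igf1r, Foxo1, Foxo3 and Foxo4 in each of the 34 libraries by group, with a line for the mean and a bar for the SD. Foxo4 averaged 6.56 CPM in QKO and 152 in Qlox, whereas Igf1r averaged 18.6 CPM in both MIGIRKO and IRIGFRlox.

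A pair of knockout libraries lay with the other genotype. Across genes, which are not independent replicates, the library labelled MIRKO 4 correlated most closely with MIGIRKO 3 (r = 0.981), and the library labelled MIGIRKO 6 with MIRKO 3 (r = 0.973). On 40 genes that separate the IRlox from the IRIGFRlox controls, on a scale with IRIGFRlox at 0 and IRlox at 1, MIRKO 1 to 3 lay at 0.959 to 1.04 and the library labelled MIRKO 4 at 0.566. MIGIRKO 1 to 5 lay at 0.626 to 0.782 on that scale and the library labelled MIGIRKO 6 at 1.02. Both libraries stay in the groups their labels give.

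**Figure D2:**
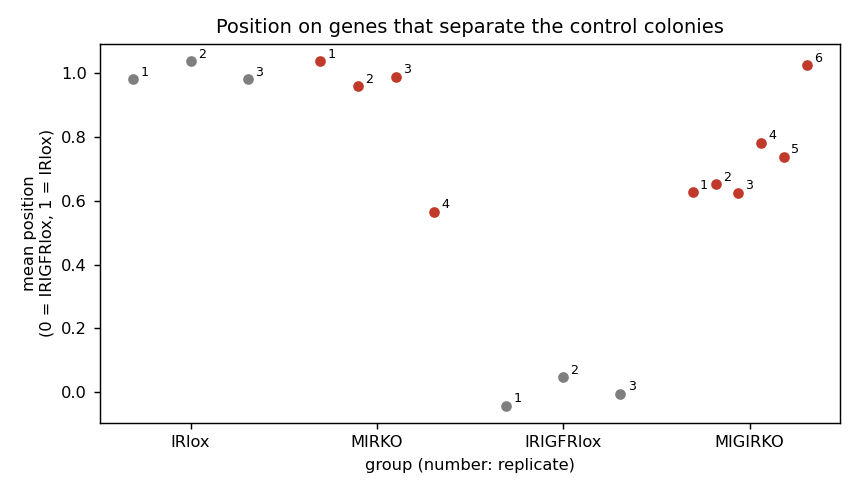
Mean position of each IRlox, MIRKO, IRIGFRlox and MIGIRKO library on 40 genes chosen from the control libraries, scaled so that the IRIGFRlox mean is 0 and the IRlox mean is 1. The library labelled MIRKO 4 lay at 0.566, below MIRKO 1 to 3 (0.959 to 1.04), and the library labelled MIGIRKO 6 at 1.02, above MIGIRKO 1 to 5 (0.626 to 0.782).

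MIRKO against IRlox asks what the loss of the insulin receptor alone changes. Of these groups, only MIRKO 1 and IRlox 2 came from the same run of library numbers, so genotype and library run can hardly be told apart. In these libraries, some transcripts of oxidative metabolism were lower in MIRKO and some of denervated or embryonic muscle higher. As many genes were called in 2 of 35 splits of the libraries, so chance could not be excluded. Myoglobin (Mb), which stores oxygen in muscle fibers, fell 3.17-fold (log2 change -1.67 ± 0.29, n = 4 against 3, adjusted p = 0.0054). Myogenin (Myog), a transcription factor of muscle differentiation that rises after denervation, was 15.8 ± 12.9 CPM against 3.69 ± 1.17 (adjusted p = 0.029). In all, 170 genes were called, 52 higher and 118 lower. With library totals only, 279 were called, 229 higher and 50 lower, so the balance of directions depends on the scaling.

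Several lists of oxidative genes were lower in MIRKO by the list test at the preset correlation, though few of their members were called over all genes. As many lists were called in 2 of 35 splits (22, highest other 23), so chance could not be excluded. Of 36 subunits of complex I, the enzyme that takes electrons from NADH, 2 were called lower over all genes and 18 adjusted over the list alone. Their median log2 change was -0.75, and -0.40 with library runs as a block (camera adjusted p = 3.8e-15 and 1.4e-10), with adjusted p = 0.10 with an estimated correlation. The called subunits were Ndufa8 (-0.74 ± 0.19, adjusted p = 0.040) and Ndufs1 (-0.53 ± 0.13, adjusted p = 0.040). Mitochondrially encoded mRNAs had a median of -0.69, with mt-Nd2 called (-1.01 ± 0.23, adjusted p = 0.029) and 8 of 13 lower adjusted over the list alone (camera adjusted p = 1.8e-05, and adjusted p = 0.13 with an estimated correlation). Complex IV had a median of -0.64 (-0.34 with library runs as a block) and 1 called member of 24, Cox5a (-0.83 ± 0.20, adjusted p = 0.035), with 2 lower adjusted over the list alone (camera adjusted p = 4.6e-06, and adjusted p = 0.13 with an estimated correlation). In the TCA cycle list, 4 of 18 genes were called lower over all genes and 15 adjusted over the list alone, among them Mdh2 (-0.74 ± 0.18, adjusted p = 0.038) and Pdhx (-0.72 ± 0.16, adjusted p = 0.029). That list had a camera adjusted p of 1.9e-12 and adjusted p = 0.10 with an estimated correlation. Cpt2, which releases fatty acids for oxidation inside mitochondria, was 41.9 ± 8.06 CPM against 72.1 ± 0.27 (adjusted p = 0.0041). It was the called member of 24 fatty acid oxidation genes, 4 of which were lower adjusted over the list alone (camera adjusted p = 1.0e-05, and adjusted p = 0.10 with an estimated correlation).

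Among 17 denervation and embryonic muscle genes, 5 were called higher in MIRKO and 14 adjusted over the list alone, with a median log2 change of 1.91 (camera adjusted p = 4.2e-09, and adjusted p = 0.10 with an estimated correlation). They included Chrna1, the muscle acetylcholine receptor subunit (2.42 ± 0.62, adjusted p = 0.046), Runx1, a transcription factor induced by denervation (2.21 ± 0.51, adjusted p = 0.031), and Ncam1, an adhesion molecule (1.19 ± 0.27, adjusted p = 0.029). Their mean log2 CPM was 3.40 to 3.88 in IRlox, 4.43 to 4.69 in MIRKO 1 to 3 and 6.23 in the library labelled MIRKO 4. Immune cell markers had a median of 1.13, with 0 of 18 called by edgeR over all genes or adjusted over the list alone (camera adjusted p = 1.2e-06, and adjusted p = 0.22 with an estimated correlation).

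Other genes with large changes in MIRKO were Igf2, a fetal growth factor (3.37 ± 0.79, adjusted p = 0.034), and the amino acid transporter Slc38a1 (3.10 ± 0.73, adjusted p = 0.035). Lower were Mss51, a mitochondrial protein of muscle (5.54 ± 2.50 against 38.7 ± 8.58 CPM, adjusted p = 0.0070), the secreted peptide Ostn (-2.59 ± 0.43, adjusted p = 0.0038), the cadherin Cdh4 (-2.75 ± 0.57, adjusted p = 0.019) and Gadd45b (-2.22 ± 0.48, adjusted p = 0.025). In the insulin and IGF signalling list, the receptor adaptor Grb14 fell (-1.77 ± 0.33, adjusted p = 0.0069), as did Igfbp5, an IGF-binding protein (-1.07 ± 0.19, adjusted p = 0.0054). The cell cycle inhibitor Cdkn1a rose (1.69 ± 0.41, adjusted p = 0.035). Pfkfb1, which makes a regulator of glycolysis, fell (-0.94 ± 0.21, adjusted p = 0.029).

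Without the libraries labelled MIRKO 4 and MIGIRKO 6, 33 genes were called in MIRKO (8 higher, 25 lower), and calls were lost both where the log2 change shrank, as for Igf2 (1.71), Chrna1 (1.24), Myog (1.33, adjusted p = 0.15), Cdkn1a (1.04), Slc38a1 (2.16), Pfkfb1 (-0.74) and Ndufs1 (-0.40, adjusted p = 0.17), and where it stayed about as large, as for Runx1 (2.11), Ncam1 (1.01), Gadd45b (-2.03), Ndufa8 (-0.79, adjusted p = 0.090), mt-Nd2 (-1.03), Cox5a (-0.73), Pdhx (-0.64) and Mdh2 (-0.66). Library totals with no scaling factor moved the median of all genes up by 0.27 and ended the calls of Ndufa8, Ndufs1, Cox5a, mt-Nd2, Pdhx and Mdh2, and the count was 13 without the library labelled MIRKO 4 alone, 368 without MIRKO 2, 9 with the compared groups only (which also ended the calls of Cpt2, Grb14 and Igfbp5, each at adjusted p = 0.10, Gadd45b and Cdkn1a) and 74 with library runs as a block, which ended the calls of Ndufa8 (adjusted p = 0.10), Ndufs1 (0.059), Cox5a (0.057), mt-Nd2 (0.079), Pdhx (0.068), Mdh2 (0.12), Chrna1 (0.12), Runx1 (0.067), Myog (0.052), Ncam1 (0.054), Igf2 (0.12), Slc38a1 (0.17), Cdh4 (0.059) and Pfkfb1 (0.079).

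MIGF1RKO against IGFRlox asks the same of the IGF-1 receptor. Here 84 genes were called, 36 higher and 48 lower, and none of the respiratory chain lists was called. Of all lists, 4 were called at the preset correlation, and 69 of 100 splits of the libraries called as many. The other splits called a median of 6, so chance could not be excluded for these lists. Mss51 fell 7.73-fold, to 7.69 ± 1.62 CPM (n = 5) from 59.9 ± 18.2 (n = 4, adjusted p = 0.00096). Chrna1 rose 4.80-fold (adjusted p = 0.047). Sytl2, a protein of vesicle transport, rose to 16.7 ± 3.60 CPM from 4.32 ± 0.49 (adjusted p = 0.00022).

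Of the 36 complex I subunits, edgeR called 0 in MIGF1RKO over all genes and 0 adjusted over the list alone, and their median log2 change was -0.02 (camera adjusted p = 0.78). Ndufa13 had the smallest adjusted p (-0.46, adjusted p = 0.49). The supercomplex list likewise had 0 called members, and its member Cox7a2l, which joins complexes III and IV, had a change of -0.91 ± 0.29 (adjusted p = 0.18). Denervation genes had 1 called higher, Chrna1, and 1 lower, Musk, the kinase that organises the neuromuscular junction (-0.90 ± 0.21, adjusted p = 0.033), with 4 higher and 1 lower adjusted over the list alone. Their median was 0.75 (camera adjusted p = 0.0015, and adjusted p = 0.97 with an estimated correlation). Slow fiber genes had a median of -0.57 with 0 called, and 1 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.0071, and adjusted p = 0.97 with an estimated correlation). The slow myosin Myh7 had a change of -1.15 ± 0.32 (adjusted p = 0.10). Cytosolic ribosomal proteins had a median of 0.24 with 0 of 75 called over all genes or adjusted over the list alone (camera adjusted p = 0.00060, and adjusted p = 0.97 with an estimated correlation).

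Glycolysis and glycogen genes in MIGF1RKO had a median near -0.22 and 1 called member, over all genes and adjusted over the list alone (camera adjusted p = 0.020, and adjusted p = 0.97 with an estimated correlation). That member was Ppp1r3c, which brings a phosphatase to glycogen (-1.40 ± 0.34, adjusted p = 0.048). Other genes that rose were Shisal1 (2.58 ± 0.52, adjusted p = 0.0089), the calcium channel subunit Cacnb4 (2.39 ± 0.52, adjusted p = 0.023), the calcium release channel Ryr3 (1.84 ± 0.43, adjusted p = 0.032) and the fatty acid desaturase Scd2 (0.83 ± 0.19, adjusted p = 0.029). Odf3l2 (-3.31 ± 0.50, adjusted p = 0.00096), Ostn (-2.30 ± 0.37, adjusted p = 0.0010), the potassium channel subunit Kcnab1 (-2.20 ± 0.35, adjusted p = 0.0010) and Actr3b (-2.05 ± 0.40, adjusted p = 0.0083) fell. The count was 176 with the compared groups only, 401 with all 12 floxed libraries as control, 30 without IGFRlox 2 and 164 without the libraries labelled MIRKO 4 and MIGIRKO 6. Library runs as a block ended the calls of Chrna1 (adjusted p = 0.051), Ryr3 (0.052), Musk (0.081) and Ppp1r3c (0.13).

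MIGIRKO against IRIGFRlox asks what the loss of both receptors, as labelled, changes, although the Igf1r deletion is not visible in these counts. Genes of energy metabolism were lower in MIGIRKO muscle, and transcripts of fat, nerve, immune cells and connective tissue were higher. Ndufs1, the largest subunit of complex I, fell to 284 ± 16.1 CPM (n = 6) from 532 ± 25.7 (n = 3, adjusted p = 1.9e-06). Adipoq, the adipocyte hormone adiponectin, rose to 49.8 ± 17.4 CPM from 8.47 ± 0.37 (adjusted p = 5.8e-05). Myog rose to 23.9 ± 6.16 CPM from 2.40 ± 0.86 (adjusted p = 6.6e-06). In all, 4603 genes were called, 2321 higher and 2282 lower, and 2093 of them changed at least 2-fold.

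These directions are relative to the TMM scaling. With library totals only, the median of all genes moved up by 0.49 on the log2 scale, and the count became 7002 (6314 higher, 688 lower). Of the genes called with TMM scaling, 3009 were called again in the same direction. Another 357 changed sign, whether or not they were called there. Complex I kept a median below 0 (-0.33), with 5 of its 21 called genes still called lower, and the TCA cycle a median of -0.25. Medians of the mitochondrial ribosome (0.09), fatty acid oxidation (0.11), mitochondrial biogenesis (0.14) and proteasome (0.24) lists turned positive, and those of complex I assembly and branched-chain amino acid catabolism came to lie at 0.00.

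In MIGIRKO 24 lists were called at the preset correlation, and 9 of 84 splits of the libraries called as many. The other splits called a median of 13, so chance could not be excluded for the list calls. In the respiratory chain of MIGIRKO, 21 of 36 complex I subunits were called lower over all genes and 24 adjusted over the list alone, with a median log2 change of -0.81 (camera adjusted p = 1.5e-08, and adjusted p = 0.19 with an estimated correlation). Ndufa8 was an example (-0.91 ± 0.17, adjusted p = 0.00012). Among 16 complex I assembly factors, 9 were lower by either adjustment (over all genes and adjusted over the list alone), led by Ecsit (-1.12 ± 0.16, adjusted p = 4.4e-06). That list had a camera adjusted p of 0.00010 and adjusted p = 0.16 with an estimated correlation. Mitochondrially encoded mRNAs had 7 of 13 members lower, also adjusted over the list alone, including mt-Nd2 (-1.27 ± 0.21, adjusted p = 2.6e-05) and mt-Nd5 (-0.94 ± 0.17, adjusted p = 0.00012), with a median of -0.92 (camera adjusted p = 0.00010, and adjusted p = 0.19 with an estimated correlation). Of 15 supercomplex and cristae factors, 7 were lower and 9 adjusted over the list alone, among them Opa1, which fuses inner mitochondrial membranes (-0.99 ± 0.14, adjusted p = 3.4e-06, camera adjusted p = 0.00028, and adjusted p = 0.14 with an estimated correlation). Complex III had 9 of 14 lower, and 10 adjusted over the list alone (camera adjusted p = 3.5e-05, and adjusted p = 0.14 with an estimated correlation). Complex V had 10 of 18 lower, also adjusted over the list alone (camera adjusted p = 0.00010, and adjusted p = 0.19 with an estimated correlation). Complex II had 5 of 8 lower, also adjusted over the list alone (camera adjusted p = 0.0099, and adjusted p = 0.19 with an estimated correlation). Complex IV had 7 of 24 lower and 1 higher, and 9 lower and 3 higher adjusted over the list alone (camera adjusted p = 0.012, and adjusted p = 0.40 with an estimated correlation). Of 76 mitochondrial ribosomal proteins, 22 were lower, and 20 adjusted over the list alone (camera adjusted p = 6.2e-06, and adjusted p = 0.30 with an estimated correlation).

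Fuel pathways were lower in MIGIRKO as well. In the TCA cycle, 15 of 18 genes were called lower, also adjusted over the list alone, with a median of -0.74 and a camera adjusted p of 1.5e-09 (adjusted p = 0.14 with an estimated correlation). They included the citrate synthase Cs (-0.71 ± 0.12, adjusted p = 2.7e-05), whose call ended with library totals only (-0.22, adjusted p = 0.064). Of 23 glycolysis and glycogen genes, 19 were lower, and 20 adjusted over the list alone, with a median of -0.96 (camera adjusted p = 1.2e-09, and adjusted p = 0.14 with an estimated correlation). Examples were the phosphorylase kinase subunit Phka1 (-1.80 ± 0.25, adjusted p = 4.0e-06) and Ppp1r3c (-2.36 ± 0.35, adjusted p = 9.1e-06). Fatty acid oxidation had 9 of 24 lower, and 10 adjusted over the list alone, with Cpt2 at 36.8 ± 4.12 against 63.3 ± 1.30 CPM (adjusted p = 1.6e-05). That list had a camera adjusted p of 0.00088 and adjusted p = 0.19 with an estimated correlation. Branched-chain amino acid catabolism had 13 of 21 lower, and 15 adjusted over the list alone, among them the kinase Bckdk (-1.06 ± 0.18, adjusted p = 5.3e-05, camera adjusted p = 5.1e-06, and adjusted p = 0.14 with an estimated correlation).

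Muscle fiber genes changed in both directions. Fast fiber genes had 12 of 15 lower, and 13 lower and 1 higher adjusted over the list alone (median -1.09, camera adjusted p = 1.8e-05, and adjusted p = 0.16 with an estimated correlation), and Myh4 fell 2.76-fold (adjusted p = 4.0e-06). Slow fiber genes had 2 higher and 4 lower of 12, with 2 and 5 adjusted over the list alone. Casq2, a calcium store protein of slow fibers, rose (1.87 ± 0.34, adjusted p = 0.00011), and Mb fell 5.11-fold (adjusted p = 1.6e-07). Of 17 denervation and embryonic muscle genes, 14 were higher and 1 lower, also adjusted over the list alone, with a median of 3.16 (camera adjusted p = 2.4e-07, and adjusted p = 0.14 with an estimated correlation). Runx1 rose to 36.7 ± 6.92 from 3.76 ± 0.63 CPM (adjusted p = 2.7e-05), and Ankrd1, a stress-responsive protein of the sarcomere, to 146 ± 42.2 from 7.26 ± 3.61 (adjusted p = 8.0e-05). The mean log2 CPM of the denervation list was 3.39 to 3.52 in IRIGFRlox, 5.85 to 6.00 in MIGIRKO 1 to 5 and 4.96 in the library labelled MIGIRKO 6. Sln, which restrains the calcium pump, was 71.0 ± 61.3 CPM in MIGIRKO and 0.27 ± 0.24 in IRIGFRlox (adjusted p = 0.0019), but was not called by limma-voom (adjusted p = 0.16).

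Markers of other cell types were higher in MIGIRKO. All 10 adipocyte markers were called higher, also adjusted over the list alone, with a median of 2.62 (camera adjusted p = 2.7e-06, and adjusted p = 0.14 with an estimated correlation). Plin1, which coats lipid droplets, rose 6.85-fold (adjusted p = 3.3e-05). The adipocyte mean log2 CPM was 3.24 to 3.41 in IRIGFRlox, 4.92 to 5.94 in MIGIRKO 1 to 5 and 4.44 in the library labelled MIGIRKO 6. All 18 immune markers were called higher, also adjusted over the list alone, with a median of 2.12, among them Cd74 (1.97 ± 0.38, adjusted p = 0.00022) and Mrc1, a macrophage receptor (1.97 ± 0.42, adjusted p = 0.00075). Immune markers had a camera adjusted p of 2.3e-07 and adjusted p = 0.19 with an estimated correlation. Of 9 nerve and Schwann cell markers, 7 were higher, and 8 adjusted over the list alone (camera adjusted p = 0.00050, and adjusted p = 0.19 with an estimated correlation). Extracellular matrix genes had 19 of 25 higher, and 20 adjusted over the list alone, with Lum (1.60 ± 0.23, adjusted p = 3.9e-06) and Postn (3.11 ± 0.58, adjusted p = 0.00021) as examples. That list had a camera adjusted p of 1.3e-09 and adjusted p = 0.14 with an estimated correlation. Endothelial markers had a median of -0.11 with 1 of 10 called, and 0 adjusted over the list alone (camera adjusted p = 0.39). That gene, the VEGF receptor Flt1, was lower (-0.34 ± 0.13, adjusted p = 0.034), and with library totals only its sign turned (0.15, adjusted p = 0.36).

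In signalling and protein turnover, Grb14 (-3.09 ± 0.30, adjusted p = 1.4e-08), Igfbp5 (-1.83 ± 0.17, adjusted p = 6.5e-09) and Tbc1d1, a regulator of glucose transporter traffic (-2.00 ± 0.26, adjusted p = 2.0e-06), fell in MIGIRKO. The insulin and IGF signalling list had 7 higher and 9 lower of 31, also adjusted over the list alone (camera adjusted p = 0.35). Of 30 genes that FoxO factors are known to induce in muscle, 11 were higher and 7 lower, with 11 and 8 adjusted over the list alone, and a median of 0.23 (camera adjusted p = 0.40). The lysosomal protease Ctsl rose (1.42 ± 0.28, adjusted p = 0.00024), whereas the autophagy kinase Ulk1 (-0.97 ± 0.17, adjusted p = 4.7e-05) and the proteasome activator Psme4 (-1.43 ± 0.22, adjusted p = 1.4e-05) fell. Autophagy genes had 3 higher and 9 lower of 39, with 3 and 8 adjusted over the list alone. Their median was 0.04 and their mean -0.08, and the test pointed down (camera adjusted p = 0.39). The proteasome list had 1 higher and 6 lower of 36, with 1 and 5 adjusted over the list alone (camera adjusted p = 0.041, 0.085 with library runs as a block, and adjusted p = 0.41 with an estimated correlation). Mstn, the growth inhibitor myostatin, fell (-2.85 ± 0.37, adjusted p = 2.0e-06), as did Amd1, an enzyme of polyamine synthesis (52.0 ± 25.4 against 774 ± 200 CPM, adjusted p = 1.3e-06). Odf3l2 (-6.10 ± 0.55, adjusted p = 1.0e-08) and Mss51 (-4.80 ± 0.44, adjusted p = 1.5e-08) had some of the largest decreases.

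**Figure D3:**
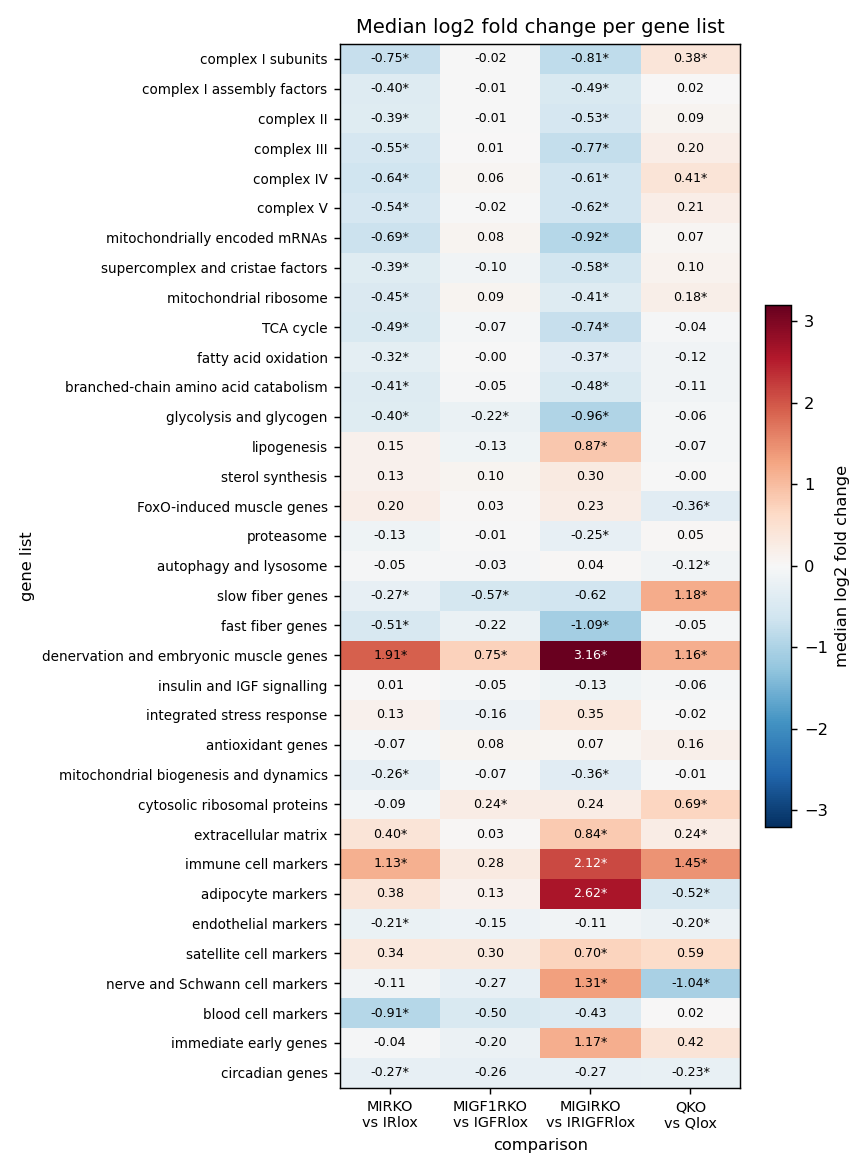
Median log2 fold change of the tested members of each of the 35 gene lists in the 4 knockout comparisons, with a star where the camera test at the preset correlation was called. Complex I had medians of -0.75 in MIRKO, -0.02 in MIGF1RKO, -0.81 in MIGIRKO and 0.38 in QKO. With library runs as a block, its QKO median turned negative and that call ended. Among starred lists, library totals only turned positive the MIGIRKO medians of the mitochondrial ribosome, fatty acid oxidation, mitochondrial biogenesis and proteasome lists (0.09, 0.11, 0.14 and 0.24). The same setting turned positive the MIRKO medians of endothelial (0.06) and slow fiber genes (0.01). A star alone does not exclude chance. Splits of the libraries other than the real one called a median of 11 lists for MIRKO, 6 for MIGF1RKO and 13 for MIGIRKO.

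**Figure D4:**
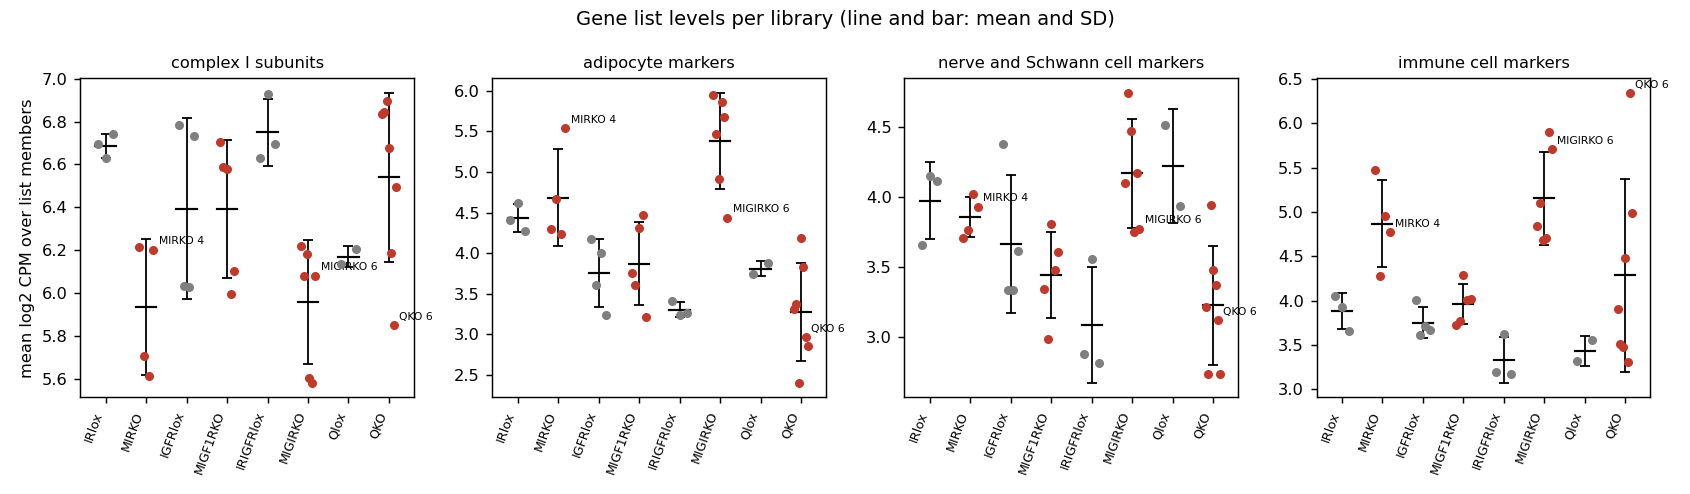
Mean log2 CPM over the members of 4 gene lists in each of the 34 libraries by group, with a line for the mean and a bar for the SD. In MIGIRKO complex I lay between 5.58 and 6.22 and the immune markers between 4.69 and 5.90, against 6.63 to 6.93 and 3.17 to 3.62 in IRIGFRlox.

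QKO against Qlox asks what remains when FoxO1, FoxO3 and FoxO4 are lost together with both receptors, as labelled, although the Foxo3 deletion is not visible in these counts. Only QKO 5 and QKO 6 came from the runs of library numbers that held Qlox, so genotype and library run are hard to tell apart here too. Fewer genes passed the test here, 69 in all with 7 higher and 62 lower, and genes that FoxO factors induce were among the lower ones. Pik3ip1, an inhibitor of PI3-kinase and a FoxO target, fell 4.57-fold, to 8.81 ± 1.95 CPM (n = 7) from 39.4 ± 2.34 (n = 2, adjusted p = 5.2e-07). Tspan8, a tetraspanin of the cell surface, fell 10.8-fold (adjusted p = 0.00037). Aqp4, the water channel of fast fibers, rose 2.64-fold (adjusted p = 0.0031).

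Of the 30 FoxO-induced genes, 3 were called lower in QKO and 7 adjusted over the list alone, with a median of -0.36 (camera adjusted p = 1.0e-05, and adjusted p = 0.15 with an estimated correlation). Besides Pik3ip1 they were Zfand5, a ubiquitin-binding protein (-0.82 ± 0.19, adjusted p = 0.039), and Sesn1, an inhibitor of mTORC1 (-1.10 ± 0.27, adjusted p = 0.048). Complex I subunits had a median of 0.38, with 0 of 36 called by edgeR over all genes or adjusted over the list alone (camera adjusted p = 0.0014, and adjusted p = 0.68 with an estimated correlation). With library runs as a block, that median turned negative and the list call ended, as given below. Their mean log2 CPM was 6.13 to 6.20 in Qlox, below every IRlox and IRIGFRlox library but within the range of IGFRlox (6.03 to 6.78). It was 5.85 in QKO 6 and at least 6.19 in the other QKO libraries. Ndufc2, a membrane subunit of complex I, was 77.4 ± 22.3 CPM against 33.2 ± 1.02 (adjusted p = 0.18). The TCA cycle had a median of -0.04 (camera adjusted p = 0.65). With library runs as a block it was called lower (median -0.17, camera adjusted p = 0.013).

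Slow fiber genes had a median of 1.18 in QKO (0.66 with library runs as a block), with 0 of 12 called over all genes by edgeR and 6 higher adjusted over the list alone (camera adjusted p = 1.7e-08, and adjusted p = 0.17 with an estimated correlation). Among them Atp2a2, the calcium pump of slow fibers, was 824 ± 156 against 463 ± 12.9 CPM (adjusted p = 0.15). Denervation genes had a median of 1.16 (0.76 with library runs as a block), with 0 of 17 called and 6 higher adjusted over the list alone (camera adjusted p = 0.0020, and adjusted p = 0.58 with an estimated correlation). Cytosolic ribosomal proteins had a median of 0.69, with 0 of 75 called over all genes or adjusted over the list alone (camera adjusted p = 7.0e-12, and adjusted p = 0.47 with an estimated correlation). Nerve and Schwann cell markers went the other way, with a median of -1.04, 0 of 9 called and 6 lower adjusted over the list alone (camera adjusted p = 1.1e-07, and adjusted p = 0.17 with an estimated correlation). Adipocyte markers had a median of -0.52, with 0 of 10 called and 1 lower adjusted over the list alone (camera adjusted p = 0.019, and adjusted p = 0.68 with an estimated correlation). Immune markers had a median of 1.45 with 0 of 18 called over all genes or adjusted over the list alone (camera adjusted p = 9.3e-05, and adjusted p = 0.58 with an estimated correlation). Their mean log2 CPM was 6.34 in QKO 6, 3.31 to 4.98 in the other QKO libraries and 3.31 to 3.55 in Qlox.

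Further genes that fell in QKO were Maob, which oxidises monoamines (4.63 ± 1.40 against 25.8 ± 5.71 CPM, adjusted p = 1.7e-07), Kcnab1 (-3.06 ± 0.39, adjusted p = 7.8e-06), and Fdft1, a squalene synthase (-1.11 ± 0.23, adjusted p = 0.011). Gpx3, a secreted peroxidase (104 ± 28.2 against 209 ± 36.2 CPM, adjusted p = 0.043), Tsc1, an inhibitor of growth signalling (-0.67 ± 0.16, adjusted p = 0.043), and the axonal protein Dpysl5 (-2.51 ± 0.38, adjusted p = 0.00023) were lower too. Myod1, a master regulator of myogenesis (2.20 ± 0.53, adjusted p = 0.048), the motor protein Kif5c (2.16 ± 0.44, adjusted p = 0.010), Mfhas1 (1.62 ± 0.34, adjusted p = 0.011) and Map3k7cl (1.52 ± 0.27, adjusted p = 0.0019) were higher. Dpysl5 and Map3k7cl also differed between the floxed groups. Library totals only ended the calls of Igf1r, Zfand5, Sesn1, Tsc1, Gpx3 and Myod1, and the count was 22 without Qlox 1, 21 without Qlox 2, 41 with the compared groups only and 135 without the libraries labelled MIRKO 4 and MIGIRKO 6. Library runs as a block ended the calls of Igf1r, Zfand5 (adjusted p = 0.12), Sesn1 (0.062), Tsc1 (0.14), Gpx3 (0.10), Myod1 (0.085) and Mfhas1 (0.057) and the list calls of complex I, whose median turned to -0.10 (camera adjusted p = 0.085), cytosolic ribosomal proteins (median 0.09, adjusted p = 0.43) and adipocyte markers (adjusted p = 0.074).

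The difference between the QKO and MIGIRKO changes sets each genotype against its own colony's controls. By the labels, it tests whether losing the FoxO factors alters the effect of losing both receptors. Besides Foxo1 and Foxo4, Igf1r itself differed (-1.09 ± 0.33, SE, log2, adjusted p = 0.042), and Foxo3 did not (-0.12, adjusted p = 0.89). By transcript, the contrast therefore does not isolate the loss of the FoxO factors. Genes of oxidative metabolism and of muscle fibers differed toward higher in QKO, and genes of fat and nerve toward lower. Ndufs1 fell in MIGIRKO, and its change in QKO was higher than in MIGIRKO by 0.76 ± 0.19 (SE, log2, adjusted p = 0.016), and that of Mb by 2.45 ± 0.43 (adjusted p = 0.0015). Plin1 differed by -3.52 ± 0.65 (adjusted p = 0.0020) and the myelin gene Mbp by -2.45 ± 0.54 (adjusted p = 0.0083). In all, 786 genes differed, 493 toward higher in QKO and 293 toward lower. Of the 4603 genes called in MIGIRKO, 721 differed.

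Complex I was a group with a called difference, as 9 of 36 subunits differed toward higher over all genes and 27 adjusted over the list alone. Its median difference was 1.10 (camera adjusted p = 4.2e-14, and adjusted p = 0.10 with an estimated correlation). Ndufc2 (2.21 ± 0.48, adjusted p = 0.0080), Ndufa8 (1.11 ± 0.27, adjusted p = 0.013) and Ndufs4 (1.37 ± 0.39, adjusted p = 0.035) were examples, and the assembly factor Ecsit differed by 1.16 ± 0.25 (adjusted p = 0.0078). Mitochondrially encoded mRNAs had 3 of 13 called, and 7 adjusted over the list alone, with mt-Nd2 at 1.36 ± 0.33 (adjusted p = 0.014, camera adjusted p = 0.00023, and adjusted p = 0.18 with an estimated correlation). The supercomplex list had 5 of 15 called, also adjusted over the list alone, with Opa1 at 0.93 ± 0.22 (adjusted p = 0.012, camera adjusted p = 7.6e-05, and adjusted p = 0.10 with an estimated correlation). The TCA cycle had 8 of 18 called and 13 adjusted over the list alone, with Mdh2 at 1.08 ± 0.27 (adjusted p = 0.014, camera adjusted p = 6.3e-10, and adjusted p = 0.087 with an estimated correlation). Glycolysis and glycogen had 8 of 23 called toward higher, and 20 higher and 1 lower adjusted over the list alone, with Pgam2 at 2.08 ± 0.48 (adjusted p = 0.011, camera adjusted p = 6.3e-10, and adjusted p = 0.10 with an estimated correlation). Slow fiber genes had 5 of 12 called and 10 adjusted over the list alone, with a median of 1.73 (camera adjusted p = 1.4e-06, and adjusted p = 0.14 with an estimated correlation), and Myh4 among the fast fiber genes differed by 1.31 ± 0.33 (adjusted p = 0.019).

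Adipocyte markers had 6 of 10 called toward lower and all 10 adjusted over the list alone, with a median difference of -3.11 (camera adjusted p = 6.3e-10, and adjusted p = 0.087 with an estimated correlation) and Adipoq at -3.16 ± 0.63 (adjusted p = 0.0041). Nerve markers had 7 of 9 called, also adjusted over the list alone, with a median of -2.28 (camera adjusted p = 2.7e-10, and adjusted p = 0.087 with an estimated correlation). FoxO-induced genes had 1 toward higher, the family member Foxo6 (2.33 ± 0.47, adjusted p = 0.0040), and 6 toward lower of 30, also adjusted over the list alone, with Pik3ip1 (-1.60 ± 0.33, adjusted p = 0.0052), Sesn1 (-1.57 ± 0.37, adjusted p = 0.012) and the lipase Pnpla2 (-1.34 ± 0.30, adjusted p = 0.0096) among them. That list had a camera adjusted p of 0.00023 and adjusted p = 0.10 with an estimated correlation. Extracellular matrix genes had 2 of 25 called toward lower and 6 adjusted over the list alone, with Lum at -1.40 ± 0.32 (adjusted p = 0.011, camera adjusted p = 1.1e-06, and adjusted p = 0.17 with an estimated correlation). In the signalling list, Igfbp5 (2.04 ± 0.28, adjusted p = 5.0e-05), Grb14 (3.00 ± 0.47, adjusted p = 0.00044) and Tbc1d1 (2.36 ± 0.43, adjusted p = 0.0019) differed toward higher in QKO. The oxidase Cyp2e1 differed toward lower (-3.93 ± 0.91, adjusted p = 0.012).

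The difference rests on a pair of Qlox libraries, and 132 genes differed without Qlox 1 and 113 without Qlox 2, but 1384 without QKO 6 and 1342 without the libraries labelled MIRKO 4 and MIGIRKO 6. Library totals only moved its median over all genes by -0.43, gave 1404 genes (166 toward higher) and ended the calls of Ndufa8 (0.66, adjusted p = 0.075), Ndufs1 (0.31, adjusted p = 0.21), Ndufs4, Opa1 and Mdh2, and library runs as a block those of Ndufa8 (0.75, adjusted p = 0.070), Ndufs4 (0.13), mt-Nd2 (0.085), Mdh2 (0.064), Myh4 (0.062) and Cyp2e1 (0.074), with the median difference of complex I at 0.53 (camera adjusted p = 9.6e-07).

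**Figure D5:**
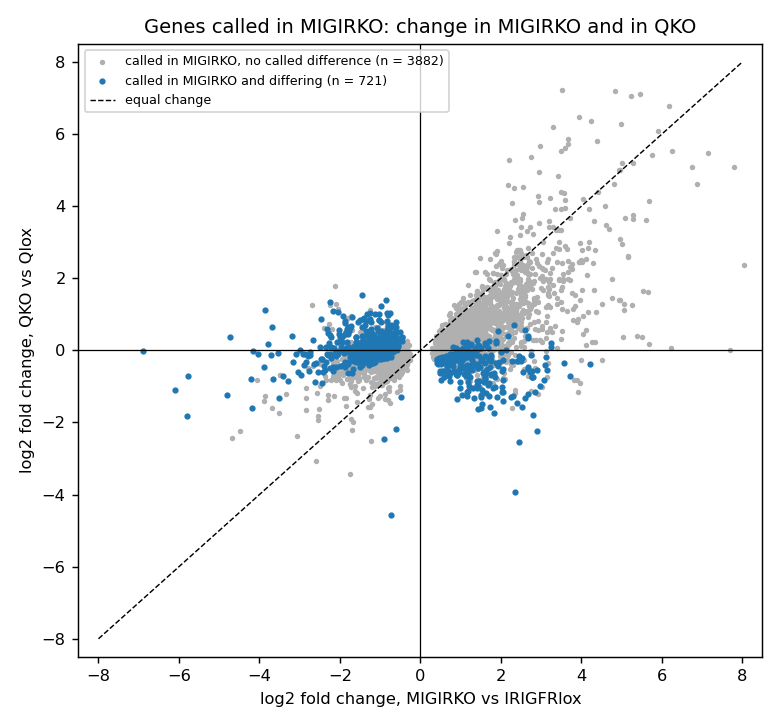
Log2 fold change in QKO against Qlox (vertical) plotted on that in MIGIRKO against IRIGFRlox (horizontal) for the 4603 genes called in MIGIRKO, with the 721 genes whose change differed in blue and equal change as a dashed line. Genes called higher in MIGIRKO had a median of 0.32 in QKO, and genes called lower in MIGIRKO a median of -0.11, against -0.76 in MIGIRKO.

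Calls of the single comparisons, which share no library, overlapped more than their numbers alone would give. MIGIRKO and MIRKO shared 162 genes called in the same direction (28.6 by chance) and 0 in the opposite one (28.8 by chance), Mb, Mss51, Grb14 and Myog among the shared. Both numbers include the libraries labelled MIRKO 4 and MIGIRKO 6, whose exchange would itself make these comparisons agree. Without them, 33 genes were called in MIRKO and 31 shared (5.63 by chance), Myog no longer among them. MIGIRKO and MIGF1RKO shared 62 (14.2 by chance) and had 2 opposite, and MIRKO and MIGF1RKO shared 21 (0.552 by chance), Mss51, Ostn and Chrna1 among them, against 123 (27.6 by chance) and 12 (0.212 by chance) without those libraries. MIGIRKO and QKO shared 35 (11.6 by chance), 33 of them lower, and had 3 opposite (11.7 by chance). Insr, targeted in both, and Foxo4, targeted in QKO, were among the 35. The overlap of MIGIRKO and QKO shrank when either Qlox library was left out. Without the libraries labelled MIRKO 4 and MIGIRKO 6, they shared 73 (23.1 by chance) and had 13 opposite (22.1 by chance). Of the genes called in MIGIRKO, the share with the same sign was 93.2% in MIRKO (87.0% without those libraries), 69.1% in MIGF1RKO and 71.0% in QKO.

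The difference between the MIGIRKO and MIRKO changes asks whether losing the IGF-1 receptor, as labelled, adds to losing the insulin receptor. Fat, nerve and matrix lists were higher in MIGIRKO by the list test at the preset correlation, while single genes did not pass. Fry called 0 lists, and 18 of 100 splits called as many lists as camera (12, highest other 20), so chance could not be excluded. EdgeR called 0 genes, with 1421 at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 16. Adipocyte markers had a median difference of 2.19, with 7 of 10 higher adjusted over the list alone (camera adjusted p = 9.0e-10, and adjusted p = 0.26 with an estimated correlation). Nerve markers had a median of 1.22, with 5 of 9 higher adjusted over the list alone (camera adjusted p = 1.9e-07, and adjusted p = 0.27 with an estimated correlation). Matrix genes had a median of 0.70, with 1 of 25 higher adjusted over the list alone (camera adjusted p = 9.0e-10, and adjusted p = 0.36 with an estimated correlation). Glycolysis and glycogen genes had a median of -0.37, with 2 of 23 lower adjusted over the list alone (camera adjusted p = 9.9e-06, and adjusted p = 0.42 with an estimated correlation). Complex I had a median of -0.03 (camera adjusted p = 0.49), but was called lower with library runs as a block (median -0.18, camera adjusted p = 0.0072).

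The libraries labelled MIRKO 4 and MIGIRKO 6 were doubted because each lay with the other genotype. Leaving them out therefore favours a larger difference between the MIGIRKO and MIRKO changes by construction and gives no separate support for it. Without them, this difference was called for 457 genes, 172 higher and 285 lower. They included Cfd, the adipocyte protease adipsin (3.63, adjusted p = 0.0035, against 2.90 and adjusted p = 0.22 with all libraries), and Agpat2, an enzyme of triglyceride synthesis (1.98, adjusted p = 0.013, against 1.69 and 0.25). They also included Ppp1r3c (-2.41, adjusted p = 0.0074, against -2.03 and 0.23), Fbxo32, the FoxO-induced ubiquitin ligase of muscle atrophy (-1.78, adjusted p = 0.0080, against -1.44 and 0.25), and Lum (1.29, adjusted p = 0.015, against 1.12 and 0.25).

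QKO against MIGIRKO directly sets the largest groups side by side, but colony and genotype cannot be told apart there. QKO muscle had higher transcripts of oxidative metabolism and lower ones of fat, among 4116 called genes, 2204 higher and 1912 lower. Complex I had 22 of 36 subunits higher and 26 adjusted over the list alone (camera adjusted p = 2.2e-08, and adjusted p = 0.18 with an estimated correlation), and Ndufs1 was higher by 0.82 ± 0.10 (adjusted p = 2.2e-07). The TCA cycle enzyme Idh3a (1.04 ± 0.13, adjusted p = 3.5e-07) and the heart and slow fiber myosin Myh6 (4.29 ± 0.41, adjusted p = 9.8e-09) were higher. Adipoq (-2.48 ± 0.32, adjusted p = 1.4e-06), Pnpla2 (-1.27 ± 0.16, adjusted p = 5.2e-07), the translation inhibitor Eif4ebp1 (-1.57 ± 0.22, adjusted p = 3.4e-06), the phosphatase Dusp26 (-3.75 ± 0.32, adjusted p = 1.0e-09) and Sln (-4.06 ± 0.94, adjusted p = 0.0016) were lower. With library totals only, the median of all genes moved by -0.39, and 6649 genes were called (754 higher, 5895 lower). Of the genes called with TMM scaling, 336 changed sign, whether or not they were called there.

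The 4 floxed groups were compared with each other to show how far colonies differ without a knockout, and 36 genes were called. They included the lysosomal enzyme Hgsnat (adjusted p = 3.3e-05), Musk (adjusted p = 0.0071), the kinase Map2k7 (adjusted p = 0.0076), Myh6 (adjusted p = 0.013) and Sdha, the catalytic subunit of complex II (adjusted p = 0.044). Leaving out 1 floxed library gave 15 to 42 genes, with 16 without IRlox 1 and 15 without IRlox 2.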

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

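In this part, the tests of swapped labels and of a shared library run, the Foxo4, depth and endothelial tests, and the tests of a few abundant genes were chosen after the results were seen, and the test of swapped labels was tried in several forms. The prediction for the lymphocyte test was written before its result, and so was that for the complex I count with library totals only, a setting itself chosen after the data were seen.

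In 85 checks of a single library against the others of its group, 5 stood apart, and chance would set apart about 1 in 20. The mean log2 CPM of the denervation genes was 6.23 in the library labelled MIRKO 4 (4.43 to 4.69 in MIRKO 1 to 3) and 4.96 in the library labelled MIGIRKO 6 (5.85 to 6.00 in MIGIRKO 1 to 5). The mean log2 CPM of the TCA cycle genes was 8.07 in QKO 6 and 8.47 to 8.68 in the other QKO libraries. Foxo1 was 6.95 log2 CPM in IGFRlox 3 (6.13 to 6.22 in the other IGFRlox libraries) and 5.95 in MIGF1RKO 2 (5.22 to 5.32 in the other MIGF1RKO libraries). Changes also differed between groups in 3 tests of the difference itself. The QKO and MIGIRKO changes differed for 786 genes and, at the preset correlation, 25 gene lists, and the MIGIRKO and MIRKO changes for 12 gene lists. With an estimated correlation 0 lists were called in either. For the 12 lists, fry called 0 and 18 of 100 splits called as many, so chance could not be excluded.

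The libraries labelled MIRKO 4 and MIGIRKO 6 each lay with the other genotype, and exchanged labels may be the reason. On 40 genes that separate the control colonies, the library labelled MIRKO 4 lay at 0.566, near MIGIRKO 1 to 5 (0.626 to 0.782), and the library labelled MIGIRKO 6 at 1.02, within MIRKO 1 to 3 (0.959 to 1.04). Both come from the same run of library numbers, but they deviated from their groups in opposite directions (-0.429 and 0.340), which argues against a shared shift. A search for genes that separated the other libraries of both colonies found Ccr9, Gm11814 and Hist1h2al, on 3 chromosomes, with both libraries on the other colony's side at each. Mixed background and breeding between colonies were not tested and stay open, since MIGIRKO 1 to 5 do not lie at 0 and the closest controls of every MIGIRKO library among the 4 floxed groups were IRlox.

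QKO 6 lay apart from the other QKO libraries, with 17 of 18 immune markers above all of them, such as Lyz2 (2072 CPM against at most 405) and Adgre1, a macrophage marker (135 against at most 25.3). Its Foxo4 level of 2.59 log2 CPM lay among the other QKO libraries (2.46 to 3.40) and below every library of the other groups (at least 6.28), which argues against a library of another genotype. Its total count of 5383932 lay within the range of the other QKO libraries (1499025 to 6605874), which argues against depth. Whether lymphoid tissue in the sample could be the source was not decided, as the mean log2 CPM of 12 lymphocyte markers was 0.285, above the other QKO libraries (-0.454 to -0.0400) by less than the margin of 1 set beforehand, and 10 of the 12 had at most 5 counts in QKO 6. A look at single markers afterwards found Ighm at 29.8 CPM against up to 87.0 and Il7r at 14.1 against at most 4.79, and an illness or injury of that mouse was not tested.

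In MIGIRKO, adipocyte, nerve and immune markers were higher and complex I genes lower. A lower share of muscle fiber RNA would raise the markers of every other cell type, but the 10 endothelial markers had a median log2 change of -0.107 (quartiles -0.330 and 0.0524), below the lowest of the other 3 medians (1.31), which argues against it as the whole cause. Lower counts of a few abundant muscle genes could shift the scaling, but this moves all other genes together. The 37 markers had a median log2 change that differed from that of all genes by 1.93 (quartiles 1.37 and 2.53), and by 1.94 with library totals only. The 36 complex I genes had one that differed by -0.848 (quartiles -0.942 and -0.646), and by -0.853 with library totals only. Scaling leaves such gaps nearly as they are by construction, so it cannot have made them. They restate the pattern, however, and are no separate test of it. With library totals only, 5 of 21 complex I subunits were still called lower, few enough to meet the prediction for scaling, but that setting moves all genes alike, so the direction of complex I against library totals stays open and whether the subunits fell per muscle fiber cannot be read from relative counts. More fat, nerve or immune cells in this genotype stay open as a biological change that was not tested.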

How the results depend on the processing

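Tests with library totals only, without the libraries labelled MIRKO 4 and MIGIRKO 6, and without QKO 5 and QKO 6 were chosen after the results were seen. DESeq2 size factors and the CPM filter left each count within 1.5 times. The DESeq2 test gave 367 genes for MIRKO (170 in the edgeR fit), 141 for MIGF1RKO (84), 139 for QKO (69), 16 for MIGIRKO minus MIRKO (0), 160 between floxed groups (36) and 79 shared by MIGIRKO and QKO (35). The limma-voom test gave 18 between floxed groups. With no filter, 102 were called for MIRKO and 498 for QKO minus MIGIRKO (786), and with library runs as a block 74 for MIRKO. With library totals only, the counts were 279 for MIRKO, 7002 for MIGIRKO (4603), 1404 for QKO minus MIGIRKO, 6649 for QKO against MIGIRKO (4116) and 19 shared by MIGIRKO and QKO, and Flt1 in MIGIRKO turned to 0.15. With all 12 floxed libraries as control they were 2944 for MIRKO, 401 for MIGF1RKO, 1105 for QKO and 783 shared by MIGIRKO and QKO. With the compared groups only they were 9 for MIRKO, 176 for MIGF1RKO, 41 for QKO, 502 for QKO minus MIGIRKO, 119 between floxed groups and 23 shared by MIGIRKO and QKO.

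Without the libraries labelled MIRKO 4 and MIGIRKO 6, the counts were 33 for MIRKO, 164 for MIGF1RKO, 135 for QKO, 1342 for QKO minus MIGIRKO, 457 for MIGIRKO minus MIRKO and 73 shared by MIGIRKO and QKO. Without QKO 5 and QKO 6, 1352 differed for QKO minus MIGIRKO. Camera with an estimated correlation called 0 lists in each of the 7 comparisons and 0 over all of them, and fry called 0 for MIGF1RKO (4 with the preset correlation), 3 for QKO (14) and 0 for MIGIRKO minus MIRKO (12). Except where fewer libraries, genes or shared spread enter by construction, the cause was not tested.

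Leaving out 1 library gave 13 to 368 genes for MIRKO, with 22, 17 and 39 without IRlox 1, 2 and 3, and 286, 368, 39 and 13 without MIRKO 1, 2, 3 and 4. For MIGF1RKO it gave 30 to 81, with 30 without IGFRlox 2, 41 without IGFRlox 4, and 45, 47 and 34 without MIGF1RKO 1, 2 and 3. The range was 3109 to 4542 for MIGIRKO and 21 to 85 for QKO, with 22 without Qlox 1 and 21 without Qlox 2. For QKO minus MIGIRKO it was 113 to 1384, with 132 without Qlox 1, 113 without Qlox 2, 450 without IRIGFRlox 1, 496 without IRIGFRlox 3, 1384 without QKO 6 and 1201 without MIGIRKO 6. For MIGIRKO minus MIRKO it was 0 to 145, with 145 without MIRKO 4 and 13 without MIGIRKO 6. It was 3508 to 5357 for QKO against MIGIRKO, and 15 to 42 between floxed groups, with 16, 15, 18, 21, 18 and 17 without IRlox 1, IRlox 2, IGFRlox 2, IGFRlox 4, Qlox 1 and Qlox 2. Between 12 and 44 genes were shared by MIGIRKO and QKO, with 15 without Qlox 1 and 12 without Qlox 2, and 6 to 7 targeted results were called. With 1 Qlox library left, it is assumed to vary like the other groups. Called lists ranged from 19 to 23 for MIRKO, 2 to 5 for MIGF1RKO (2 without IGFRlox 1 or IGFRlox 2), 23 to 26 for MIGIRKO, 11 to 15 for QKO, 23 to 27 for QKO minus MIGIRKO, 8 to 14 for MIGIRKO minus MIRKO and 24 to 28 for QKO against MIGIRKO.

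Of 177 results for genes taken from those the rule names, 158 were called. Of these calls, 38 were lost with library runs as a block, 33 with the compared groups only, 23 with limma-voom and 20 with no filter. Library totals only ended 23 with the sign kept, besides that of Flt1, whose sign turned. Without the libraries labelled MIRKO 4 and MIGIRKO 6, 19 were lost. The depth of QKO 5 (1499025 counts) and the number of Qlox libraries may limit what QKO can show. Without QKO 5, however, 85 genes were called in QKO (69 with all libraries). Of 67 genes simulated with a 1.5-fold change, 7.46% were recovered in QKO and 14.9% in MIGIRKO, which does not separate depth from group size.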

Other observations

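All tests of other splits in this part were planned, and none was chosen after its result was seen. Genes of fat synthesis were mostly higher in MIGIRKO, in the same libraries in which all 10 adipocyte markers were higher (mean log2 CPM 5.38 against 3.30), so these counts do not place the change in muscle fibers. In MIGIRKO, 12 of 19 lipogenesis genes rose and 3 fell, with 13 and 3 adjusted over the list alone (median log2 change 0.87, camera adjusted p = 0.0040, and adjusted p = 0.21 with an estimated correlation). Scd2, a fatty acid desaturase, rose to 89.3 ± 13.9 CPM (n = 6) from 41.0 ± 5.57 (n = 3, edgeR adjusted p = 9.9e-05). Of 22 genes of the integrated stress response, which slows translation under amino acid shortage, 7 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.059, and called higher with library runs as a block, adjusted p = 0.026), and the asparagine synthetase Asns rose 3.41-fold (adjusted p = 0.00085). Satellite cell markers had 3 of 8 higher, also adjusted over the list alone (camera adjusted p = 0.016, and adjusted p = 0.14 with an estimated correlation), among them Vcam1 (27.4 ± 2.72 against 6.63 ± 1.12 CPM, adjusted p = 1.6e-05). Immediate early genes had 6 of 15 higher, also adjusted over the list alone (camera adjusted p = 0.025, and adjusted p = 0.36 with an estimated correlation), with Junb at 2.12 ± 0.52 (SE, log2, adjusted p = 0.0023).

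Mitochondrial biogenesis and dynamics genes had 8 of 22 lower in MIGIRKO, and 10 adjusted over the list alone (camera adjusted p = 0.00016, and adjusted p = 0.14 with an estimated correlation), and the nuclear receptor Esrrb was lower (-2.22 ± 0.34, adjusted p = 1.3e-05). Circadian genes had 4 of 17 lower, also adjusted over the list alone (camera adjusted p = 0.11). Antioxidant genes had 3 higher and 3 lower of 23, with 2 and 3 adjusted over the list alone. Their median was 0.07 and the test pointed down (camera adjusted p = 0.91). Sterol synthesis had 2 higher and 1 lower of 19, with 1 and 0 adjusted over the list alone (camera adjusted p = 0.21). Cytosolic ribosomal proteins had 3 of 75 higher, and 1 adjusted over the list alone (camera adjusted p = 0.066), and the list was called higher with library runs as a block (median 0.44, adjusted p = 2.1e-07). Of 6 blood cell markers edgeR called 0 over all genes or adjusted over the list alone (camera adjusted p = 0.41).

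The same libraries were also split into other groups of the same sizes, to see how often as many genes or lists were called. For MIGIRKO, 1 of 84 splits, the real one, called as many genes, and no other split came near (4603, highest other 798). For MIGF1RKO, 1 of 100 splits did, again the real one (84, highest other 19). For QKO against MIGIRKO, 2 of 100 did, and the other one, with QKO 6 and MIGIRKO 3 exchanged, called more (4127 against 4116). Such splits do not tell genotype from colony or library run. For MIRKO, 2 of 35 splits called as many genes (170), and the highest other, with MIRKO 2 placed among the IRlox libraries, called 234, so chance could not be excluded. For MIGIRKO minus MIRKO, the count of 0 genes is reached by all 100 splits whatever they call (highest other 274), so the splits say nothing about it. Gene lists were called as often in 2 of 35 splits for MIRKO (22, highest other 23), 69 of 100 for MIGF1RKO (4, highest other 18), 9 of 84 for MIGIRKO (24, highest other 25) and 18 of 100 for MIGIRKO minus MIRKO (12, highest other 20), which does not exclude chance. For QKO against MIGIRKO 3 of 100 splits called as many lists (26, highest other 28), so chance is less likely there but not excluded. Splits other than the real one called a median of 11 lists for MIRKO, 6 for MIGF1RKO and 13 for MIGIRKO. That median was 14 for QKO against MIGIRKO and 6 for MIGIRKO minus MIRKO. List calls at the preset correlation were therefore common in other groupings too. Comparisons that use the pair of Qlox libraries were not split.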
